A study of Rattus norvegicus with 9 samples.

How the data were processed

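RNA of the adrenal medulla was measured on 9 Affymetrix rat oligonucleotide arrays, 3 from unstressed rats (control), 3 from rats immobilized in 1 session (IMO_1x) and 3 from rats immobilized in 6 daily sessions (IMO_6x). The labels do not say whether each array holds the RNA of a separate animal, so the p-values measure the spread between these 9 samples. The organism is given as Rattus norvegicus, and other label fields that name mouse or brain were not followed.

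The deposited table holds 1 intensity per probe set and array on a linear scale, and per the labels the arrays were labelled and run by the manufacturer. The trimmed mean of each array, with the lowest and highest 2% of values left out, lay between 2500.6 and 2501, so each array had been scaled as a whole before deposit. The medians were not equal. They were 1053, 954.7 and 910.5 in the 3 control arrays, 974.7, 863.7 and 826.3 in the IMO_1x arrays and 1583, 592.6 and 674.6 in the IMO_6x arrays. The method that summarised probes into probe sets, its background step and the scaling target are not given in the sources used here, so how the scale treats dim and bright probe sets stays unknown. The values were not centred per probe set. No detection calls and no raw probe intensities were used here. For arrays, the number of arrays limits the precision. No genome build is named with the values, so no coordinates are given.

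The table holds 31099 probe sets, of which 57 are array controls. An annotation table gave 1 gene symbol to 20826 of the others, several symbols to 436 and none to 9780. Probe sets with several symbols or none were left out of the gene tests. Of 21268 annotated probe sets, 20764 had a gene identifier in the current gene table, and 0 symbols changed on updating. The named probe sets covered 14217 genes. Values were transformed as log2(value + 16), the dimmest 30% of probe sets by mean level were left out, and the probe set with the highest mean level stood for each gene, which left 11287 genes.

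Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with all 9 arrays in 1 fit, no covariates and 6 residual degrees of freedom. The 3 comparisons were IMO_1x against control, IMO_6x against control and IMO_6x against IMO_1x. The last is also the test of whether the responses to 1 and to 6 sessions differ. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Errors of fold changes are standard errors (SE) of the fit, which is shared by the 3 groups, and errors of levels are standard deviations (SD) over 3 arrays. The share of genes whose groups of 3 arrays do not overlap is 10% by chance, as an average over splits. Genes vary together and the array medians differ, so the share in 1 split can lie far from 10% without a response.

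Gene groups were tested with camera of limma, at a preset correlation between genes of 0.01, over 21 lists and 3 comparisons, with adjustment over all 63 tests. Camera sets the test statistics of the members against those of all other genes tested. Its direction can therefore be up for a list whose median log2 fold change is below 0. The lists were catecholamine synthesis and storage, immediate early transcription factors, neuropeptides and processing, exocytosis machinery, receptors and channels of excitation, MAPK and cAMP feedback, heat shock chaperones, unfolded protein response, glucocorticoid-induced genes, inflammatory cytokines and targets, circadian clock, cholesterol synthesis and uptake, cell cycle, growth factors and angiogenic signals, and markers of adrenal cortex, Schwann cells and glia, endothelium, leukocytes, fibroblasts and matrix, erythrocytes and adipocytes. A few genes stand in more than 1 list. The glucocorticoid-induced list shares 3 members with other lists, the immediate early and inflammatory lists 2 each, and the MAPK and cAMP, circadian and Schwann lists 1 each. Each list was also tested with a correlation estimated from the arrays, with fry and on ranks. Counts of members that pass are given over all genes tested and adjusted over the list alone.

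The groups, the tests, the lists, the other settings to try and the rule for named genes were set before the data were examined. The rule takes the 10 genes with the largest rise and the 10 with the largest fall against control (5 each way between the stressed groups) among those past the threshold without overlap between the groups. It adds up to 4 members of each list with the smallest adjusted p, and Th, Dbh and Pnmt in every comparison. Members that moved against the rest of their list, such as Arc and Nr0b1, were named after their values were seen. The other settings were no filter or a filter of 50%, quantile normalization, median centring, pseudocounts of 1 and 64, adjusted p thresholds of 0.01 and 0.1, a fold threshold of 1.5, array weights, other choices of probe set, a replicate block, fits of only the 2 groups compared, and leaving out each array in turn. Leaving out IMO_6x replicate 1 together with quantile normalization, and the replicate block with the control and IMO_1x arrays alone, were added after the data were seen. After each other normalization or pseudocount the brightest probe set was chosen anew, so a gene's value there can come from another probe set.

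Whether replicate numbers pair the samples was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. For IMO_1x and control the correlations were 0.508, 0.36 and 0.25 for numbers 1, 2 and 3. For IMO_6x and control they were 0.142, 0.06 and 0.158. The labels name no shared day or litter, and the replicate number was used as a block only as an alternative. The procedure was tested on 20 draws of simulated data, with 200 changed genes among 11287 independent genes, each with 1 spread on all 9 arrays. It recovered 18.6% of genes changed by 1 on the log2 scale, 73.6% of those changed by 2, 87.8% by 3 and 95.1% by 4, and 6.2% of its calls were false. Because both stressed groups share the same 3 controls, the correlation of their fold changes and the count of genes changed in both were set beside 50 simulated draws of unchanged groups. Array controls were compared between groups with an exact two-sided permutation test, whose smallest p with 3 arrays against 3 is 0.1. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.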

Results

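The adrenal medulla, the core of the adrenal gland that secretes adrenaline and noradrenaline, was taken from adult rats of 280 to 320 g, and its RNA was measured on 9 oligonucleotide arrays. Rats of 3 arrays were not stressed. Rats of 3 arrays were immobilized once for 2 h (IMO_1x), and rats of 3 arrays for 2 h daily on 6 days (IMO_6x), with the tissue taken after the last session. The values are intensities scaled per array to trimmed means between 2500.6 and 2501, and 11287 genes were tested. The number of arrays, 3 per group, limits the precision.

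The IMO_6x arrays differed from the others in the array controls, so RNA quality and 6 sessions go together in each comparison with IMO_6x. Leaving out IMO_6x replicate 1 does not part them, since IMO_6x replicates 2 and 3 differed too. Differences from control of 2 probe sets of the same gene correlated at 0.481 for IMO_6x replicates 2 and 3 and at 0.758 for IMO_1x. The actin 3′/5′ ratio, a measure of how complete the labelled RNA is, was 231, 6.11 and 8.87 in IMO_6x replicates 1, 2 and 3, against 1.45 to 2.15 in control and 1.57 to 1.99 in IMO_1x. The GAPDH 3′/5′ ratio was 5.02, 1.79 and 1.87, against at most 1.41 in the other 6 arrays. On the log2 scale the actin difference was 4.54 ± 2.88 (SD, n = 3) in IMO_6x and 0.86 ± 0.29 in control (exact permutation p = 0.1, the smallest 3 against 3 arrays allow). Spike-in controls averaged a log2 level of 17.69, 14.27 and 14.67 in IMO_6x and 12.33 to 13.31 in control, 2.80 higher in IMO_6x (exact permutation p = 0.1) and 0.09 higher in IMO_1x (exact permutation p = 0.9). IMO_6x replicate 1 correlated with the other arrays at 0.604 to 0.730 across genes, while the other 8 correlated with one another at 0.854 to 0.983. The first principal component held 42.7% of the variance and placed this array at 125.1, with the others between -36.2 and 7.5.

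**Figure D1:**
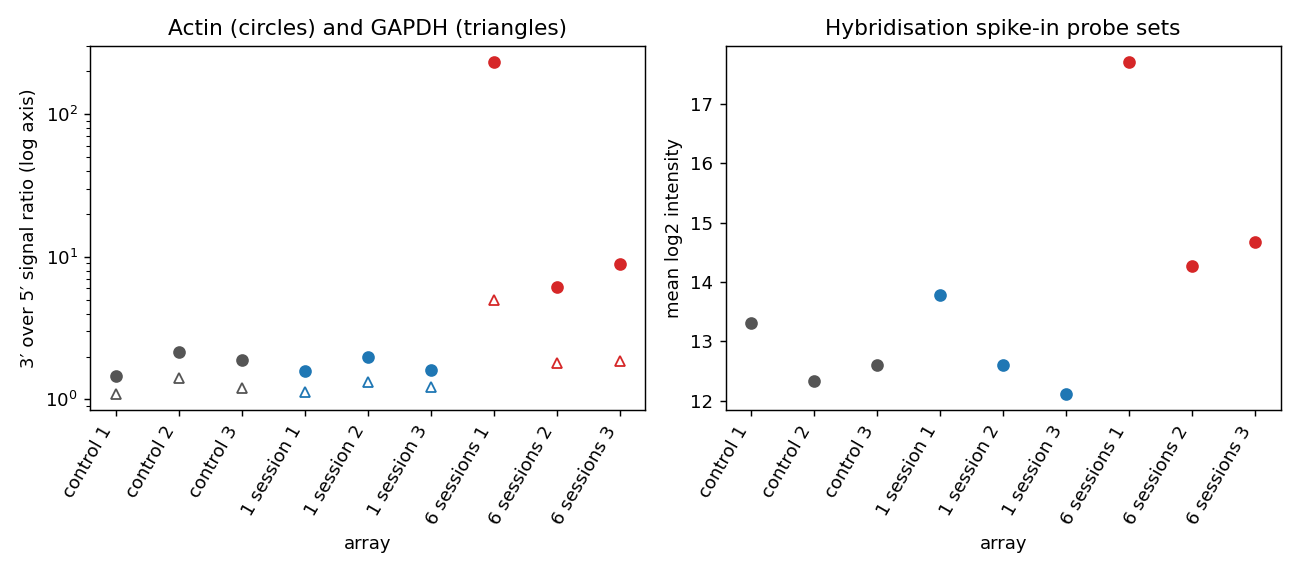
Actin and GAPDH 3′/5′ ratios (log axis) and the mean log2 intensity of the spike-in controls, 1 point per array, by group. IMO_6x replicate 1 has an actin ratio of 231, and the other 2 IMO_6x arrays, at 6.11 and 8.87, also lie above all control and IMO_1x arrays.

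What a first session of immobilization does to the transcripts of the dissected medulla is the question of IMO_1x against control. On each of the 9 arrays the mean log2 level of the adrenal cortex markers lay above that of the catecholamine list, by 0.325 to 1.205. The samples thus held cortex RNA in all groups, and a change is not by itself one of medulla cells. The 10 largest rises past the threshold were those of Iqub, Fosb, Nr4a3, Olr1, Fam110c, Inhba, Phlda1, Calca, Giot1 and Ackr3. Fosb, a partner of Jun proteins in the AP-1 factor, rose by 7.35 ± 0.34 (SE) on the log2 scale, from a level of 5.80 ± 0.14 to 13.15 ± 0.28 (SD, n = 3 each, adjusted p = 8.54e-06). The size of the rise depends on the constant added before taking logs, with 7.80 at the lower and 6.46 at the higher one tried. Nr4a3, an orphan nuclear receptor, rose by 6.17 ± 0.33 (4.67 to 6.50 over its alternatives). Inhba, the subunit of activin A, rose by 5.30 ± 0.44 (3.63 to 5.60), and Calca, the gene of calcitonin and CGRP, by 5.07 ± 0.34 (4.45 to 5.36). The immediate early list rose as a group, with 18 of 23 measured members up, 0 down and 5 not past the threshold (median log2 fold change 2.45, 2.58 above that of all genes, adjusted p = 5.61e-27, and 0.0011 with an estimated correlation). Adjusted over the list alone, 19 passed. Maff rose by 4.73 ± 0.29 (SE) and Klf4 by 3.38 ± 0.20.

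Feedback regulators of MAPK and cAMP signalling rose with them, 15 of 17 members and 0 down (median 1.99, adjusted p = 5.39e-23, and 0.0168 with an estimated correlation), 16 of them adjusted over the list alone. Nfil3 rose by 4.37 ± 0.23, Gem, a small GTPase, by 3.46 ± 0.25, Sik1, a kinase induced by cAMP, by 3.40 ± 0.25 and the phosphatase Dusp5 by 2.65 ± 0.24. In the list of inflammatory cytokines and targets 6 of 10 rose and 0 fell (median 1.62, adjusted p = 1.14e-09, and 0.0106 with an estimated correlation), 8 adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, rose by 4.04 ± 0.53 and Ccl2, a monocyte chemokine, by 2.71 ± 0.38. Neuropeptides and their processing rose as a group with 3 of 13 members past the threshold, Calca, Nts (4.81 ± 0.57) and Vgf (4.06 ± 0.50), and 5 adjusted over the list alone (median 0.77, adjusted p = 4.59e-08, and 0.127 with an estimated correlation). Without IMO_6x replicate 1, which enters the shared spread, 8 of these 13 rose and 0 fell. Then 17 of 17 feedback members and 8 of 10 inflammatory members rose, and 0 fell. Galanin, Gal, had a log2 fold change of 1.16 ± 0.33 (adjusted p = 0.0553).

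Further lists rose with smaller medians. Of 12 heat shock chaperones 4 rose and 0 fell (5 adjusted over the list alone, median 0.57, adjusted p = 2.75e-05, and 0.291 with an estimated correlation), with Hspa1a at 3.20 ± 0.34 and Hspb8 at 2.87 ± 0.40. Of 16 glucocorticoid-induced genes 5 rose and 0 fell (7 adjusted over the list alone, median 0.67, adjusted p = 2e-04, and 0.235 with an estimated correlation), among them Ddit4 at 2.57 ± 0.37. Of 11 genes of cholesterol synthesis and uptake 4 rose and 0 fell, 4 adjusted over the list alone (median 0.41, adjusted p = 0.0018, and 0.481 with an estimated correlation). One of them, Insig1, a sterol sensor, rose by 2.07 ± 0.40, with an adjusted p of 0.058 without control replicate 2 and 0.0545 without control replicate 3 (6.95e-06 to 0.147 over its alternatives). Of 9 growth factors and angiogenic signals 2 rose and 0 fell, 2 adjusted over the list alone (median 0.41, adjusted p = 0.0121, and 0.154 with an estimated correlation), among them Bdnf, which rose 16-fold (log2 fold change 2.46 with the mean of all its probe sets). The cholesterol median was 0.24 without IMO_1x replicate 1, and that of growth factors 0.26 without control replicate 3. Without IMO_6x replicate 1, 6 heat shock chaperones rose and 0 fell, and 8 glucocorticoid-induced genes rose and 2 fell. In that setting 4 cholesterol genes rose and 1 fell, and 2 growth factors rose and 1 fell. The growth factor list had an adjusted p of 0.0661 with the dimmest 50% of the probe sets left out and 0.0641 with quantile normalization without IMO_6x replicate 1, in a range of 0.00191 to 0.154 over its alternatives.

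The list of catecholamine synthesis and storage did not pass as a group after 1 session (median 0.15, adjusted p = 0.141, 1 of 14 rose, 1 adjusted over the list alone). Th, the rate-limiting enzyme of catecholamine synthesis, had a log2 fold change of 0.18 ± 0.47, Dbh, which makes noradrenaline, 0.15 ± 0.47 and Pnmt, which makes adrenaline, 0.35 ± 0.34. Gch1, which makes the cofactor of Th, rose by 2.01 ± 0.45 (adjusted p = 0.0227). Its adjusted p was 0.0519 with the replicate number as a block, 0.103 and 0.11 without control replicates 2 and 3, and 0.084, 0.085 and 0.0664 without IMO_1x replicates 1, 2 and 3, in a range of 1.79e-06 to 0.227 over its alternatives. The list itself passed without control replicate 1 (adjusted p = 0.0301), without IMO_1x replicate 3 (adjusted p = 0.0212) and by the test on ranks (0.0494), with 0.0212 to 0.714 over its alternatives. Its median was 0.35 and 0.38 without these 2 arrays, and -0.11 without IMO_1x replicate 1.

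Exocytosis machinery (median 0.29, adjusted p = 0.141) passed without control replicate 2 (median 0.54, adjusted p = 0.0412) and with array weights (0.0309, with 0.0309 to 0.568 over its alternatives), and markers of adrenal cortex (median -0.04, adjusted p = 0.152) without IMO_1x replicate 3 (median 0.25, adjusted p = 0.0139, 0.0139 to 0.806 over its alternatives). Leaving out 1 array gave medians of 0.19 to 0.54 for exocytosis and of -0.35 to 0.25 for the cortex markers. The other lists not past the threshold had medians of -0.02 for receptors and channels of excitation (adjusted p = 0.473), 0.13 for the unfolded protein response (0.381), -0.13 for the circadian clock (0.545, with 3 of 14 up and 1, Dbp, down) and -0.30 for the cell cycle (0.54). Markers of Schwann cells and glia had a median of 0.29, endothelium 0.01, leukocytes -0.04, fibroblasts and matrix 0.02, erythrocytes -0.10 and adipocytes 0.06, with adjusted p from 0.265 to 0.897 over these 6 lists. The test direction was up for the receptor, circadian, cortex, leukocyte and erythrocyte lists although their medians were below 0. The circadian mean was -0.10. The cortex mean was 0.18 and that of fibroblasts and matrix -0.02, each of the opposite sign to its median. The median log2 fold change of all genes was -0.13, and 0 with each array centred on its median.

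In all, 474 genes rose and 599 fell by limma, each of these 1073 without overlap between the 3 stressed and the 3 control arrays, and 401 and 398 of them by at least 2-fold. Of all genes, 42.9% had no overlap, against 10% by chance on average over splits. The largest falls included Shpk, a sugar kinase (log2 fold change -3.38 ± 0.41), Cxcr4, the receptor of the chemokine CXCL12 (-3.32 ± 0.30), and Sbk1, a kinase (-2.91 ± 0.33), while Ackr3, the other receptor of CXCL12, rose by 4.95 ± 0.25. Quantile normalization gave 460 rises and 347 falls, and centring on the median 158 and 67, where Hspb8 and Ddit4 no longer passed the threshold. Of the 1073 genes, 700 kept call and direction under quantile normalization. The count was 3388 without IMO_6x replicate 1, because the 3 groups share 1 estimate of the spread, 655, 418 and 360 without control replicates 1, 2 and 3, and 599, 462 and 402 without IMO_1x replicates 1, 2 and 3.

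**Figure D2:**
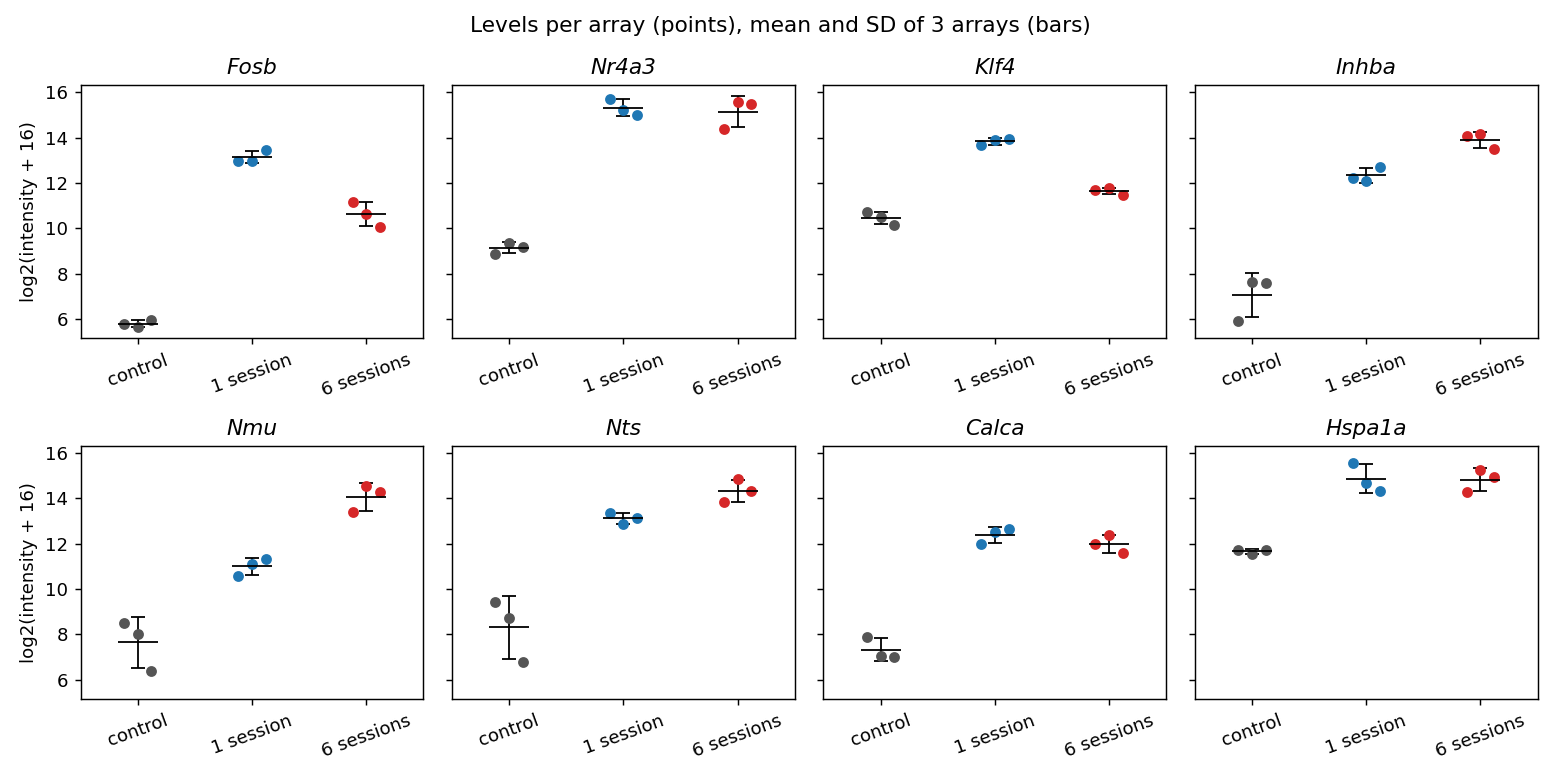
Log2 intensity of 8 genes on each of the 9 arrays (points) with the group mean and SD (bars, n = 3). Fosb is at 5.80 ± 0.14 in control, 13.15 ± 0.28 in IMO_1x and 10.63 ± 0.54 in IMO_6x, and Nmu at 7.65 ± 1.12 in control and 14.08 ± 0.61 in IMO_6x.

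IMO_6x against control asks what stands after 6 daily sessions. The 10 largest rises past the threshold with all arrays were those of Inhba, Nmu, Nts, Nr4a3, Cbln2, Myo16, Fam110c, Crem, Iqub and Fosb. Inhba rose by 6.86 ± 0.44 (SE) on the log2 scale, from a level of 7.05 ± 0.97 to 13.91 ± 0.36 (SD, n = 3 each, adjusted p = 3.14e-05), with 5.11 to 7.15 over its alternatives. Nmu, neuromedin U, rose by 6.44 ± 0.53 (5.80 to 6.99) and Nts, neurotensin, by 6.03 ± 0.57 (5.26 to 6.59). Of 13 measured neuropeptide and processing genes 12 rose and 0 fell (13 adjusted over the list alone, median log2 fold change 1.74, adjusted p = 4.02e-11, and 0.0734 with an estimated correlation). Calca rose by 4.66 ± 0.34, Vgf by 4.38 ± 0.50 and Cpe, an enzyme that trims peptide hormones, by 1.77 ± 0.26. The actin 3′/5′ ratios of these IMO_6x arrays were 231, 6.11 and 8.87, and under quantile normalization without IMO_6x replicate 1 the Cpe change was 0.48.

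Immediate early genes were above control after 6 sessions, with 14 of 23 members up and 1, Arc, down (15 adjusted over the list alone, median 1.45, adjusted p = 9.5e-10, and 0.0106 with an estimated correlation). Crem, a cAMP-responsive factor, rose by 5.55 ± 0.29, Nr4a3 by 6.02 ± 0.33 and Fosb by 4.83 ± 0.34. MAPK and cAMP feedback had 12 of 17 up and 0 down (13 adjusted over the list alone, median 1.68, adjusted p = 1.48e-09, and 0.0804 with an estimated correlation), with Nfil3 at 4.11 ± 0.23 and Pde4d, a cAMP phosphodiesterase, at 3.19 ± 0.33. Of 10 inflammatory cytokines and targets 4 rose and 0 fell, 4 adjusted over the list alone (median 0.75, adjusted p = 0.000907, and 0.0734 with an estimated correlation), with Stat3 at 1.57 ± 0.23. Of 16 glucocorticoid-induced genes 6 rose and 0 fell (8 adjusted over the list alone, median 0.81, adjusted p = 0.00437, and 0.366 with an estimated correlation), with Fkbp5, a co-chaperone of the glucocorticoid receptor, at 2.04 ± 0.27. The adjusted p of that list was 0.0824 with quantile normalization (0.00028 to 0.366 over its alternatives). The spike-in controls of the same IMO_6x arrays were 2.80 above control on the log2 scale.

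Of 12 heat shock chaperones 11 rose and 0 fell (11 adjusted over the list alone, median 1.52, adjusted p = 2.58e-08, and 0.155 with an estimated correlation), with Hspa1a at 3.17 ± 0.34 and Hsph1 at 2.16 ± 0.32. Under quantile normalization 7 rose, with a median of 1.00. In the unfolded protein response list 4 of 17 rose and 0 fell (5 adjusted over the list alone, median 0.23, adjusted p = 0.0154, and 0.474 with an estimated correlation), among them Hsp90b1 at 1.69 ± 0.21 and Dnajc3 at 1.61 ± 0.20, both chaperones of the endoplasmic reticulum. That list had an adjusted p of 0.0845 without IMO_6x replicate 2, 0.0582 without IMO_6x replicate 3, 0.0549 with median centring and 0.236 with quantile normalization (0.000594 to 0.474 over its alternatives). Its median was 0.63, 0.01 and 0.07 without IMO_6x replicates 1, 2 and 3, and 0.10 with quantile normalization. Of 11 cholesterol synthesis and uptake genes 6 rose and 0 fell, 6 adjusted over the list alone (median 0.72, adjusted p = 0.00134, and 0.481 with an estimated correlation), with Idi1 at 3.51 ± 0.46 and Cyp51 at 2.91 ± 0.30, and a median of 1.13 without IMO_6x replicate 1. In these IMO_6x arrays the GAPDH 3′/5′ ratio was 1.79 to 5.02.

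Transcripts of catecholamine synthesis and storage and markers of adrenal cortex, the steroid-making layer around the medulla, were both above control. In the first list 6 of 14 rose and 0 fell (9 adjusted over the list alone, median 1.07, adjusted p = 0.00531, and 0.474 with an estimated correlation), with Chgb, a granin of secretory granules, at 2.63 ± 0.56, Dbh at 2.17 ± 0.47 and Pnmt at 1.62 ± 0.34. Th had a log2 fold change of 1.29 ± 0.47 (adjusted p = 0.0741), and 1.75 without IMO_6x replicate 1 (adjusted p = 0.00185, 2.21e-05 to 0.981 over its alternatives). Of 12 cortex markers 7 rose and 1, Nr0b1, fell (9 adjusted over the list alone, median 1.40, adjusted p = 0.000689, and 0.366 with an estimated correlation). Star, the cholesterol carrier of steroid synthesis, rose by 2.58 ± 0.48 and Scarb1, the HDL receptor, by 2.63 ± 0.42. Both lists lost their call under quantile normalization, where their medians turned to -0.06 (adjusted p = 0.6, 3.67e-05 to 0.6 over its alternatives) and -0.20 (adjusted p = 0.875, 8.73e-05 to 0.875). The change of Chgb was then 0.50 and that of Star 0.72, with an adjusted p of 0.0337 (6.57e-06 to 0.0462 over its alternatives) and 0.0169 (4.9e-06 to 0.0292). The change of Dbh was then 0.29 (adjusted p = 0.214, 1.31e-05 to 0.214) and that of Pnmt 0.45 (adjusted p = 0.159, 2.72e-06 to 0.159). Dbh also had an adjusted p of 0.0502 without control replicate 3. The 3 IMO_6x arrays had actin 3′/5′ ratios of 6.11 to 231.

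In the list of receptors and channels of excitation, 2 genes rose and 3 fell of 15 (6 adjusted over the list alone), and the list did not pass (median -0.39, adjusted p = 0.524). Chrnb4 fell by 2.06 ± 0.27, and Chrna7 fell by 2.65 ± 0.48, both subunits of the nicotinic receptors through which nerves drive the medulla. The circadian list did not pass either (median -0.49, adjusted p = 0.739), with 2 of 14 up and 1 down (3 adjusted over the list alone). Cry1, a clock repressor, rose by 2.32 ± 0.38, and Npas2, a partner of Bmal1, fell by 4.05 ± 0.98. The log2 level of Npas2 was 10.82, 6.34 and 6.83 in IMO_6x replicates 1, 2 and 3 and 11.51 to 12.74 in control. Npas2 missed the threshold without control replicates 1 and 3 (adjusted p = 0.0625 and 0.0524) and in a fit of only the 2 groups (0.0535), with 6.58e-08 to 0.0625 over its alternatives. Lists with adjusted p of 0.207 to 0.908 were exocytosis machinery (median -0.12), cell cycle (0.23), growth factors and angiogenic signals (0.58) and markers of Schwann cells and glia (0.55), endothelium (-0.29), leukocytes (-0.39), fibroblasts and matrix (-0.14), erythrocytes (-0.41) and adipocytes (0.12). Without IMO_6x replicate 1 the medians were 0.45 for exocytosis, 0.14 for leukocytes and 0.46 for fibroblasts and matrix, of the opposite sign, and 0.45 for adipocytes, which had -0.09 and -0.01 without IMO_6x replicates 2 and 3. The test direction was up for exocytosis, circadian clock and fibroblasts although their medians were below 0, with a mean of 0.21 for exocytosis, -0.24 for the circadian clock and 0.16 for fibroblasts. Of the 9 growth factors and angiogenic signals 1 rose and 2 fell (3 adjusted over the list alone). Bdnf rose by 3.74 ± 0.40 (2.27 with the mean of all its probe sets). Vegfa, an angiogenic factor, fell by 0.875 ± 0.265, and Adm, adrenomedullin, fell by 1.33 ± 0.42, with changes of -0.55 and -0.76 without IMO_6x replicate 1. Vegfa passed in 11 of 22 alternatives (adjusted p from 0.00147 to 0.539) and Adm in 10 (0.0013 to 0.391). The GAPDH 3′/5′ ratios of the IMO_6x arrays were 5.02, 1.79 and 1.87.

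In all, 1057 genes rose and 1681 fell by limma, 2725 of these 2738 without overlap between the groups, and 755 and 1185 by at least 2-fold. Of all genes, 41.5% had no overlap, against 10% by chance on average over splits, and the median log2 fold change of all genes was -0.23. The largest falls included Npas2, Nr0b2, a nuclear receptor that represses transcription (log2 fold change -3.98 ± 0.51), Proser3 (-3.61 ± 0.45), Appl2, an endosomal adaptor (-3.55 ± 0.43), and Cnr1, a cannabinoid receptor (-3.57 ± 0.72, and -2.51 without IMO_6x replicate 1). Without IMO_6x replicate 1, 2016 rose and 3421 fell, and all but 1 of the 2738 genes passed again, 2737. Quantile normalization gave 1035 rises and 947 falls, centring on the median 462 and 227, and quantile normalization without IMO_6x replicate 1 1855 and 2103. Of the 2738 genes, 1626 kept call and direction under quantile normalization, and 2146 when IMO_6x replicate 1 was also left out. The count was 1724, 1474 and 1382 without control replicates 1, 2 and 3.

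**Figure D3:**
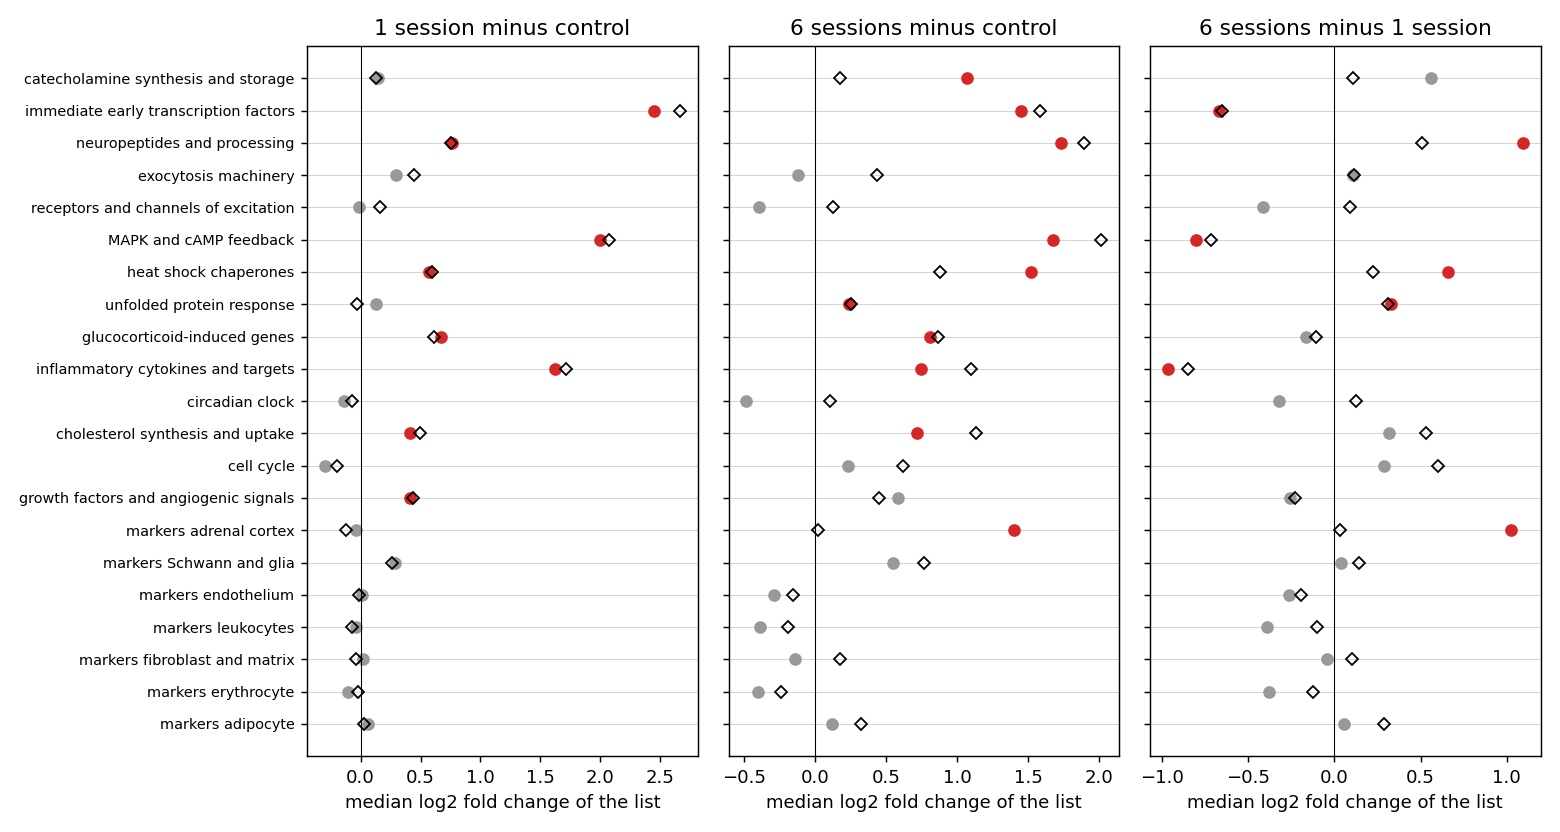
Median log2 fold change of each of the 21 gene lists in the 3 comparisons, filled red where the list passed at an adjusted p under 0.05 and grey where not, with open diamonds for quantile normalization without IMO_6x replicate 1. The cortex markers have a median of 1.40 in IMO_6x against control and a diamond at 0.02, while the immediate early list has 2.45 in IMO_1x against control.

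Whether the responses to 1 and 6 sessions differ was tested by IMO_6x against IMO_1x. Immediate early genes were lower after the sixth session than after the first, with 9 of 23 members down and 2, Jund and Crem, up (12 adjusted over the list alone, median -0.67, adjusted p = 0.000538, and 0.0631 with an estimated correlation). Klf4 fell by 2.21 ± 0.20 (SE), from a log2 level of 13.85 ± 0.16 to 11.64 ± 0.15 (SD, n = 3 each), Fosb fell by 2.52 ± 0.34 and Arc fell by 2.34 ± 0.29. The rise of Crem rests on 1 probe set, since its 5 other probe sets lay between -0.78 and 0.25. Under quantile normalization, with the brightest probe set chosen anew, Crem was at -0.12. The other 2 probe sets of Jund were at 2.10 and -0.18. Lower members depended on the probe set too. Fos was at -1.605 on the one used and -0.032 on another. Klf6 was at -1.408, with others at 0.072 and -1.093, and Jun at -0.589, with others at 0.462 and -1.408. Of 18 other probe sets of the list 12 were below 0, with a median of -0.208. Of 17 MAPK and cAMP feedback genes 6 fell and 0 rose (10 adjusted over the list alone, median -0.80, adjusted p = 0.00233, and 0.366 with an estimated correlation), with Gem at -1.78 ± 0.25 and a median of -0.49 without IMO_6x replicate 1. Of 10 inflammatory cytokines and targets 3 fell and 0 rose (6 adjusted over the list alone, median -0.97, adjusted p = 0.0446, and 0.235 with an estimated correlation), with Ccl2 at -2.22 ± 0.38. Its adjusted p was 0.0704 without IMO_1x replicate 1, 0.113 without IMO_6x replicate 1, 0.0932 without IMO_6x replicate 3 and 0.0712 with the replicate number as a block (0.00508 to 0.235 over its alternatives). The actin 3′/5′ ratio was 231, 6.11 and 8.87 in IMO_6x and at most 1.99 in IMO_1x.

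Neuropeptides and processing were higher after 6 sessions than after 1, with 5 of 13 members up and 0 down (7 adjusted over the list alone, median 1.09, adjusted p = 0.000751, and 0.343 with an estimated correlation), among them Cpe at 1.58 ± 0.26 and Pcsk2, a prohormone convertase, at 1.44 ± 0.31. Cpe was at 0.50 under quantile normalization, and at 0.41 when IMO_6x replicate 1 was also left out, and passed in 16 of 22 alternatives (adjusted p from 1.23e-05 to 0.089). Pcsk2 passed in 15 (4.98e-05 to 0.223). Under quantile normalization 1 of the 13 rose (median 0.50, adjusted p = 0.0145, 0.000226 to 0.343 over its alternatives), and 3 rose (median 0.51) when IMO_6x replicate 1 was also left out. Outside the lists Nmu rose by 3.08 ± 0.53. Of 12 heat shock chaperones 5 rose and 0 fell (7 adjusted over the list alone, median 0.66, adjusted p = 0.0123, and 0.481 with an estimated correlation), with Hspb1 at 1.18 ± 0.21. Of 17 unfolded protein response genes 5 rose and 0 fell (6 adjusted over the list alone, median 0.33, adjusted p = 0.0364, and 0.481 with an estimated correlation), with Hsp90b1 at 1.52 ± 0.21. The heat shock list had an adjusted p of 0.0532 without IMO_1x replicate 3, 0.108 without IMO_6x replicate 2 and 0.751 with quantile normalization (0.000787 to 0.751 over its alternatives), where the median was 0.09, Hspb1 was at 0.59, and Hsp90ab1 and Hspd1 turned below 0. The unfolded protein response list had 0.0533 without IMO_1x replicate 3, 0.179 and 0.137 without IMO_6x replicates 2 and 3, and 0.303 with quantile normalization (0.00138 to 0.481), with medians of 0.10, 0.16 and 0.15 in the last 3. The GAPDH 3′/5′ ratios of the IMO_6x arrays were 5.02, 1.79 and 1.87, and no test here parted the rises of these lists from RNA quality.

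Cortex markers were higher, with 4 of 12 up and 0 down (6 adjusted over the list alone, median 1.02, adjusted p = 0.00514, and 0.474 with an estimated correlation), with Star at 2.25 ± 0.48 and Hsd3b1 at 1.95 ± 0.41. Under quantile normalization Star was at 0.30 (adjusted p = 0.251, 1.41e-05 to 0.251 over its alternatives) and Hsd3b1 at 0.37 (adjusted p = 0.119, 1.58e-05 to 0.119). Without IMO_1x replicates 2 and 3 the adjusted p was 0.0917 and 0.0938 for Star, and 0.0911 and 0.0914 for Hsd3b1. Under quantile normalization the median was -0.06 (adjusted p = 0.751), and 0.03 (adjusted p = 0.896, 0.000117 to 0.896 over its alternatives) when IMO_6x replicate 1 was also left out. Catecholamine synthesis and storage had 4 of 14 members up and 0 down (5 adjusted over the list alone) and did not pass (median 0.56, adjusted p = 0.06). It passed without IMO_1x replicate 1 (adjusted p = 0.0107), without IMO_6x replicate 1 (adjusted p = 0.000572), with median centring (0.0275) and with array weights (0.000336), in a range of 0.000336 to 0.79 over its alternatives. Its median was 0.99, 0.16 and 0.31 without IMO_6x replicates 1, 2 and 3, and -0.17 under quantile normalization. Dbh rose by 2.02 ± 0.47 and Pnmt by 1.27 ± 0.34, with Th at 1.11 ± 0.47 (adjusted p = 0.16). Under quantile normalization Dbh was at 0.07 (adjusted p = 0.779) and Pnmt at -0.01 (adjusted p = 0.978). Dbh passed in 14 of 22 alternatives (adjusted p from 2.92e-05 to 0.779) and Pnmt in 8 (1.89e-05 to 0.978), and both missed the threshold without any 1 of the IMO_1x arrays (adjusted p = 0.0508, 0.102 and 0.111 for Dbh and 0.0642, 0.14 and 0.158 for Pnmt, replicates 1, 2 and 3), or without control replicate 2 (0.0553 and 0.0799) or 3 (0.0546 and 0.0809). Pnmt also missed it without control replicate 1 (0.0624), IMO_6x replicate 2 (0.0821) or IMO_6x replicate 3 (0.103), and with the replicate number as a block (0.0794). Cholesterol synthesis and uptake (median 0.32, adjusted p = 0.157) passed without IMO_1x replicate 1 (median 0.54, adjusted p = 0.0107), without IMO_6x replicate 1 (median 0.50, adjusted p = 0.00366), with quantile normalization as well (0.049) and with array weights (0.000188), in a range of 0.000188 to 0.784 over its alternatives. Leaving out 1 array gave medians of 0.13 to 0.54 for it. The spike-in controls of IMO_6x had log2 levels of 17.69, 14.27 and 14.67.

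Chrna7 fell by 2.71 ± 0.48 and Chrnb4 fell by 1.59 ± 0.27 in the receptor list, which did not pass (median -0.41, adjusted p = 0.157), except with median centring (adjusted p = 0.0479, 0.0479 to 0.568 over its alternatives). Medians of the lists with adjusted p from 0.0924 to 0.996 were 0.11 for exocytosis machinery, where the mean was -0.14 and the test direction down, -0.17 for glucocorticoid-induced genes, -0.32 for the circadian clock, 0.29 for the cell cycle and -0.26 for growth factors and angiogenic signals. The cell cycle list passed without a filter (adjusted p = 0.0422), with 50% of probe sets left out (0.0399), with median centring (0.0351), with the mean of all probe sets of a gene (0.0443) and by fry (0.0295), in a range of 0.0295 to 0.474 over its alternatives. Markers of Schwann cells and glia had a median of 0.04, endothelium -0.26, leukocytes -0.39, fibroblasts and matrix -0.04 with a mean of 0.18 and the test direction up, erythrocytes -0.38 and adipocytes 0.06. The medians of 5 of these lists had the opposite sign without IMO_6x replicate 1, at -0.18 for exocytosis, 0.14 for glucocorticoid-induced genes, 0.03 for the circadian clock, 0.003 for leukocytes and 0.56 for fibroblasts and matrix. The largest falls with all arrays were those of Cwc25, a splicing factor (log2 fold change -6.12 ± 0.66), and Trpm7, a channel with a kinase domain (-3.31 ± 0.75). Without IMO_6x replicate 1 they were -5.52 and -2.20, and Retnla, at -3.17, and Kprp, at -2.87, then lay below Trpm7. Log2 levels of Cwc25 were 9.28 to 11.44 in control, 13.86 to 15.26 in IMO_1x and 7.31 to 9.44 in IMO_6x. The IMO_6x actin 3′/5′ ratios were 231, 6.11 and 8.87.

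In all, 588 genes rose and 523 fell by limma, each of these 1111 without overlap between the groups. Of all genes, 33.8% had no overlap, against 10% by chance on average over splits. The median log2 fold change of all genes was -0.08. Without IMO_6x replicate 1, 1729 rose and 1924 fell. Without IMO_1x replicates 1, 2 and 3 the counts were 358, 8 and 0, with 2333 genes at an unadjusted p under 0.05 in the last, where Fosb, Klf4, Cpe and Hsp90b1, at -2.36, -2.15, 1.43 and 1.43, no longer passed. Counts were 733, 582 and 524 without control replicates 1, 2 and 3, 663 without IMO_6x replicate 3, 60 with median centring and 3 in a fit of only the 2 groups. Quantile normalization gave 388 rises and 243 falls, and 522 of the 1111 genes kept call and direction there.

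Genes changed against control after 1 and after 6 sessions were also compared. Of these, 317 genes rose in both groups, where 44.4 would by independent calls, and 405 fell in both, where 89.2 would. Iqub rose by 7.39 ± 0.32 after 1 session and 5.08 ± 0.32 after 6, Fam110c by 5.57 ± 0.37 and 5.60 ± 0.37, and Nr4a3 by 6.17 ± 0.33 and 6.02 ± 0.33. The 5 genes past the threshold in opposite directions were Arc, Bmp2, Cir1, Fam43a and Srf, named after their values were seen. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.626 (jackknife SD 0.09 over the 9 arrays) and a Spearman rho of 0.531, and 69.7% of genes had the same sign. Unchanged groups set against the same 3 controls gave a simulated r of 0.50, 66.7% of genes with the same sign and 0 genes past the threshold in both. The covariance was 0.433, against 0.091 simulated. The counts by independent calls leave out the shared controls, so part of the excess over them may come from these, and the simulated values hold the shared controls but no effects. The count in both was 722 with all arrays and 2255 without IMO_6x replicate 1. It was 447, 296 and 258 without control replicates 1, 2 and 3, and 436, 341 and 316 without IMO_1x replicates 1, 2 and 3.

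**Figure D4:**
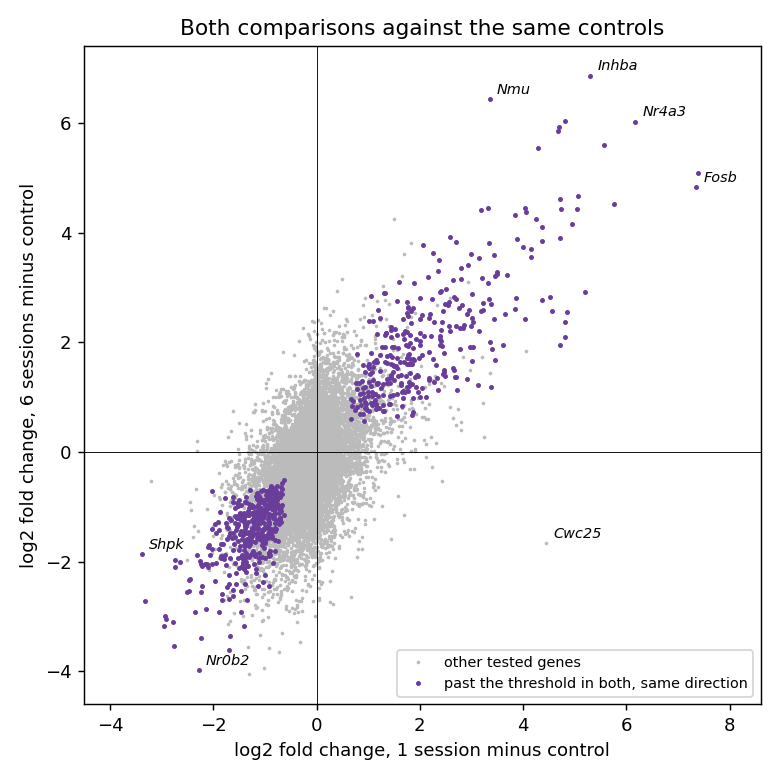
Log2 fold change of each gene after 1 session (horizontal) and after 6 sessions (vertical), both against the same 3 control arrays, with the 722 genes past the threshold in both in the same direction in purple. Fosb lies at 7.35 and 4.83, and Inhba at 5.30 and 6.86.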

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

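In this part, the tests of a wrong label, of probe sets on ordinary replicates, of a level-dependent scale in IMO_6x against control and of IMO_6x replicate 1 as the sole source of the lower immediate early genes were chosen after the result was seen. Groups of 3 arrays were not tested for an outlying array. The array controls, which no comparison uses, lay above the control arrays on 4 arrays. Spike-in controls averaged a log2 level of 13.78 in IMO_1x replicate 1 and 17.69, 14.27 and 14.67 in IMO_6x replicates 1, 2 and 3. The actin 3′/5′ ratio was 231, 6.11 and 8.87 in IMO_6x replicates 1, 2 and 3, and the GAPDH 3′/5′ ratio 5.02, 1.79 and 1.87.

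By the test of the difference itself, responses to 1 and 6 sessions differed in 1111 genes. Camera called 7 lists in this comparison. Their median log2 fold changes were -0.67 for immediate early genes, 1.09 for neuropeptides and processing and -0.80 for MAPK and cAMP feedback. Heat shock chaperones had 0.66, the unfolded protein response 0.33, inflammatory cytokines and targets -0.97 and cortex markers 1.02. With an estimated correlation camera called 0 of the 7 (adjusted p from 0.0631 to 0.481, 2 lists at an unadjusted p under 0.05), and under quantile normalization the cortex median was -0.06. Of single genes, Nmu (3.08), Nptx1 (2.74), Lrrc20 (2.68), Riok1 (2.66) and Nexmif (2.54) were higher in IMO_6x, and Cwc25 (-6.12), Trpm7 (-3.31), Kprp (-3.08), Retnla (-2.99) and Csrnp3 (-2.97) lower. Lrrc20 was at 6.46 to 6.79 in IMO_1x, and its IMO_6x levels (8.37 to 10.3) overlapped those of control (9.54 to 10.18). Csrnp3 was at 13.92 to 14.63 in IMO_1x, and its IMO_6x levels (10.55 to 11.94) overlapped control too (10.56 to 11.33). Without IMO_6x replicate 1, Trpm7 was at -2.20 and, with quantile normalization as well, Nexmif at -0.69. In the latter setting the brightest probe set was chosen anew, so the value can come from another probe set of Nexmif. On the one used in the main fit, Nexmif was at 12.47 and 12.81 in IMO_6x replicates 2 and 3 and 10.44 to 11.14 in IMO_1x. Without IMO_1x replicates 2 and 3, 8 and 0 genes passed by limma, with 2333 at an unadjusted p under 0.05 in the latter. Splits of 6 arrays into 3 and 3 are 10, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes (1073, 2738 and 1111), and the highest other gave 0. The other splits mix arrays of the 2 groups, so group differences enter the spread, and 0 calls there do not measure chance. For IMO_1x against control, deviations of same-numbered arrays correlated at 0.508, 0.36 and 0.25. Number 3 did not match its own number best, and the labels name no pairing. There the highest other among the 4 splits that part all 3 same-numbered pairs also gave 0.

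IMO_6x replicate 1 stood apart from the other arrays. Its median immediate early level lay 1.608 above the control mean, with the control arrays themselves between -0.019 and 0.003, which argues against a control array under a wrong label. Deviations of 2 probe sets of the same gene correlated at 0.175 on this array, where the IMO_1x response gave 0.758. IMO_1x replicate 1 and control replicate 1, each set against the other 2 arrays of its group, gave 0.169 and 0.272, so this correlation alone does not set the array apart. The SD of the difference between the 2 probe sets does, at 1.919 on this array against 0.772 and 0.617 on those replicates. For IMO_6x replicates 2 and 3 against control it was 1.003 (correlation 0.481), and 0.495 for the IMO_1x response. A real difference of this sample would move 2 probe sets of a gene together, so these values argue against it as the whole source. RNA cut short and poor labelling, which the actin ratio of 231 raises, cannot be told apart, and a real part stays possible.

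Abundant transcripts of 3 lists were above control in IMO_6x. A level-dependent scale of the IMO_6x arrays may account for the cortex markers, whose excess over genes of like level was 0.386, at percentile 94.11 of random lists. Heat shock chaperones had an excess of 1.482 over genes of like level, at percentile 100, which argues against that scale as their whole source. Outside these 3 lists, the unfolded protein response had an excess of 0.272 (percentile 89.43), and 0.322 (percentile 95.72) without IMO_6x replicate 1. The scale may thus account for its rise too. For catecholamine synthesis and storage the excess was 0.185 (percentile 81.81), and 0.473 (percentile 99.98) without IMO_6x replicate 1, so the scale and a response cannot be told apart for this list. More cortex in the IMO_6x dissections cannot be told apart either, because the cortex list minus the catecholamine list was 0.138 higher than in control, within a spread of 0.44 (SD, n = 3, exact permutation p = 0.7).

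Immediate early genes were lower in IMO_6x than in IMO_1x. Without IMO_6x replicate 1 the median was -0.4641, so that array was not the sole source. Against genes of like level the list's excess was -1.031 with all 9 arrays and -0.814 without that array. Both lay at percentile 0 of random lists, which argues against a level-dependent scale. RNA cut short on the IMO_6x arrays cannot be told apart, since 18 other probe sets of 10 members had a median of -0.208 with 12 of them below 0. A smaller response to a repeated session stays open as a hypothesis, which no test here separates from RNA cut short.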

How the results depend on the processing

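Quantile normalization without IMO_6x replicate 1, and the replicate block in control and IMO_1x arrays alone, were chosen after the data were seen. Of the alternatives for called named genes, 1103, 1531 and 885 kept direction and call in IMO_1x against control, IMO_6x against control and IMO_6x against IMO_1x, and 165, 177 and 358 lost the call in the same direction. For called lists 168, 197 and 121 kept both, and 8, 23 and 31 lost the call. Counts of genes in that order were 225, 689 and 60 with median centring, 4498, 6555 and 5588 with array weights, 3210, 1517 and 3 in fits of only 2 groups, and 367, 1153 and 58 at the stricter threshold. Quantile normalization gave 631 in IMO_6x against IMO_1x, and, when IMO_6x replicate 1 was also left out, 3414 in IMO_1x against control and 2489 in IMO_6x against IMO_1x. Taking every probe set gave 4323 and 1754 in the comparisons with IMO_6x, as more features were tested, the looser threshold 2034 in the last, and the replicate block in control and IMO_1x arrays alone 4340. Leaving out 1 array gave 360 to 3388, 1382 to 5437 and 0 to 3653 (2333 at an unadjusted p under 0.05 by limma). Genes changed in both were 149 with centring, 3071 with array weights, 1991 with quantile normalization without IMO_6x replicate 1, and 258 to 2255 leaving out 1 array. The correlation of fold changes was 0.531 as Spearman rho and 0.551 to 0.675 in the other alternatives. Lists called were 3, 1 and 0 with an estimated correlation by camera, and with quantile normalization 6 and 4 in the comparisons with IMO_6x. The cause of these changes was not tested except where given.

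Direction turned in IMO_6x against IMO_1x for cortex markers (median -0.0562 with quantile normalization, and 0.0330, where the test turned, when IMO_6x replicate 1 was also left out), Nexmif (-0.69, quantile without that array), Pnmt (-0.01), Hsp90ab1 (-0.16), Hspd1 (-0.025, and -0.005 without that array) and Fdx1 (-0.026, quantile), and in IMO_6x against control for Cd74 (-0.30, quantile without that array). Because the brightest probe set was chosen anew in these settings, single values, such as that of Nexmif, can come from another probe set. With quantile normalization the median alone turned below 0 for catecholamine synthesis and storage (-0.06 in IMO_6x against control and -0.17 in IMO_6x against IMO_1x) and for cortex markers in IMO_6x against control (-0.20), and so did the change of Crem in IMO_6x against IMO_1x (-0.12). Among lists not called, quantile normalization also gave medians of the other sign, in IMO_1x against control for the unfolded protein response (-0.03), fibroblasts (-0.04), endothelium (-0.01) and receptors (0.15), and for adipocytes in both comparisons with IMO_6x (-0.005 and -0.02). Medians near 0 changed sign under other alternatives too. By fry, calls were lost in IMO_1x against control for cholesterol (adjusted p = 0.163), in IMO_6x against control for catecholamine synthesis (0.158), the unfolded protein response, glucocorticoid-induced genes and cholesterol (each 0.053), and in IMO_6x against IMO_1x for heat shock (0.0554), the unfolded protein response (0.0823) and cortex markers (0.0565). They were gained for growth factors in IMO_6x against control (0.00944) and for the cell cycle in IMO_6x against IMO_1x (0.0295). The cause was not tested. With the replicate number as a block, the counts were 977, 2741 and 943, the inflammatory list lost its call in IMO_6x against IMO_1x (adjusted p = 0.0712), and 5, 4 and 4 called named genes lost theirs. Deviations of same-numbered IMO_6x and IMO_1x arrays correlated at 0.15, 0.078 and 0.088. In simulated data 18.6% of changes of 1 on the log2 scale were found, so smaller changes are mostly missed in that setting. It held independent genes, each with 1 spread on all arrays, and no outlying array. In the real data the IMO_1x count went from 1073 to 3388 without IMO_6x replicate 1. The simulated shares, also the 6.2% of false calls, therefore need not hold for these arrays.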

Other observations

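The genes of this part were picked after their values were seen, because they changed, and so were their tests. Beyond the fixed lists, some single genes of secreted peptides and hormones are given by their values. Uts2, the vasoactive peptide urotensin 2, had log2 fold changes of 4.72 ± 0.42 (SE) after 1 session and 4.62 after 6 (adjusted p = 0.000172 and 0.000192). Ucn2, urocortin 2, of the corticotropin-releasing hormone family, had 4.38 ± 0.32 and 3.84. Stc1, stanniocalcin 1, had 2.20 ± 0.31 and 2.52. Prlh, prolactin-releasing hormone, rose by 1.05 ± 0.25 after 1 session and by 2.84 after 6, a difference of 1.79 (adjusted p = 0.00952). Pdyn, the dynorphin precursor, was at 0.004 after 1 session (adjusted p = 0.997) and rose by 0.96 ± 0.22 after 6 (adjusted p = 0.0127), with a difference of 0.96 (adjusted p = 0.0279). The differences between the stressed groups rest on counts that fell to 8 and 0 without IMO_1x replicates 2 and 3, and the actin 3′/5′ ratios of the IMO_6x arrays were 231, 6.11 and 8.87.

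Of 9 measured ADAMTS proteases, which cut the extracellular matrix, 3 rose and 0 fell after 1 session, and 3 rose and 1, Adamts10, fell after 6 (4 rises each with quantile normalization without IMO_6x replicate 1). Adamts4 rose by 4.81 ± 0.37 after 1 session and 2.37 after 6, and fell by 2.44 between them (adjusted p = 0.0104). Adamts1 rose by 2.78 ± 0.21 and 1.87, and Adamts9 by 3.32 ± 0.19 and 3.07. Ptges, which makes prostaglandin E2 from the product of Ptgs2, rose by 2.70 ± 0.30 after 1 session and 3.83 after 6, and Bdkrb2, the bradykinin receptor, by 3.18 ± 0.47 and 4.42. Of the 5 genes with opposite calls, Arc was at 1.12 after 1 session and -1.22 after 6, Srf at 0.72 and -0.65, Bmp2 at 0.86 and -0.79, Fam43a at 1.05 and -0.84, and Cir1 at -0.95 and 0.92. With quantile normalization without IMO_6x replicate 1, Fam43a after 6 sessions was at -0.53 (adjusted p = 0.0826). The IMO_6x arrays had GAPDH 3′/5′ ratios of 5.02, 1.79 and 1.87.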
